A study of Mus musculus with 40 samples.

How the data were processed

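RNA of aorta and of macrophages from congenic and control Ldlr-/- mice was measured on a custom Affymetrix mouse array, with 10 arrays in each of 4 groups and 40 arrays in all. Per the labels, total RNA was amplified in plates, labelled with biotin, and hybridised, and the values were made with RMA. RMA corrects background, applies quantile normalisation across arrays and summarises each probe set by median polish, but its version, its settings and the arrays run together were not stated. The deposited values are intensities on a linear scale: all are positive and they reach 22665, so RMA values appear to have been taken back from log2. Whether they were processed further is not stated, and log2 was taken before every test. Within a tissue, the 20 columns share nearly the same distribution, while the distributions of the tissues differ by a median of 0.57 in sorted log2 values. The tissues therefore appear to have been normalised separately, and levels across tissues depend on that step more than contrasts between strains within a tissue do.

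The table held 38385 probe sets and no missing value. Probe sets were named through the platform annotation, and each gene was placed on its chromosome through its Entrez identifier in the RefSeq table of the GRCm38.p6 assembly. That table placed 24237 of the probe sets that named 1 gene. The 236 genes it did not place were left out of Fisher's test and counted as off chromosome 4 elsewhere. The deposited table names no genome build, so positions are given as chromosome and gene order only. Of the probe sets, 24478 named 1 gene, 65 named several and 13842 named none, and the last 2 kinds were left out of the tests of genes. This gave 19147 genes, of which 3958 had several probe sets. Each gene was represented by the probe set with the highest mean over the arrays of the fit, so a gene can rest on different probe sets in different fits. No filter on signal was applied.

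Comparisons were run in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, without trend or robust options), two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Congenic and control mice were compared in each tissue alone, with 10 arrays against 10. The difference of the congenic effect between the tissues (macrophages minus aorta) and the difference between control macrophages and control aorta came from a fit of all 40 arrays with 4 group means. The mouse numbers differ in all groups, so no test was paired. Whether a mouse gave both aorta and macrophages is not stated, and the fit of all 40 arrays took them as independent. Cdkn2a and Cdkn2b were also tested by two-sided permutation tests of the difference of means with 100000 resamples. Calls on chromosome 4 were compared with calls elsewhere by Fisher's exact test. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for tables, permutations and figures.

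Before the data were examined, 37 gene lists were written from textbook knowledge of macrophages, the vessel wall, the cell cycle and other cell types that a sample could hold, 17 of them marker lists. The list of erythroid markers had fewer than 5 measured genes and was not tested. Lists were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, with adjustment over the lists of a comparison. For each list, members past the threshold were counted over all genes and again with adjustment over the list alone.

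Genes named in the text followed a rule fixed before the data were examined. For each congenic comparison it took Cdkn2a and Cdkn2b, the 10 largest rises and 10 largest falls past the threshold, the 5 largest of each off chromosome 4, and up to 4 members with the smallest p of each list that passed or had a called member. For the difference between tissues it took Cdkn2a and the 10 genes with the smallest p, and for the tissue markers the 2 members of each marker list with the largest difference. The text names a part of these, and a few others that are said to have been chosen after their values were seen.

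The pipeline was tested on simulated data drawn for each gene on its own from a normal distribution with its observed mean and spread, with 50 genes shifted at each of 4 sizes. Of genes shifted by 0.5 on the log2 scale, it recovered 86% in macrophages, 80% in aorta and 72% for the difference between tissues, and of genes shifted by 1 it recovered 98%, 96% and 96%. The share of false calls was 4.48% in macrophages, 6% in aorta and 6.12% for the difference. A list of 30 genes shifted by 0.5 was recovered in each comparison. Its members were drawn without correlation, so this does not show how the list test performs on correlated genes.

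Alternatives fixed before the data were examined were a repeated quantile normalisation, centring of arrays on their medians, a filter on signal, other ways to choose among probe sets, other variance models, array weights, removal of the least correlated array of each group, all 40 arrays in the fit, stricter thresholds, and tests without the genes of chromosome 4. Added later were the Xist and Eif2s3y sets as a covariate and each alone, quantile normalisation over all 40 arrays for the tissue contrast, the macrophage marker mean as a covariate in aorta, and aorta without mouse 19. Intensities carry no counts, and the number of arrays per group is among the limits of the precision.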

Results

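RNA abundance was measured on arrays in aorta and in macrophages of Ldlr-/- mice, which lack the LDL receptor and are used as a model of atherosclerosis. The congenic strain, C57BL/6.MOLFc4(51Mb)-Ldlr-/-, carries, by its name, 51 Mb of chromosome 4 from the MOLF strain on a C57BL/6 background. The control strain was C57BL/6-Ldlr-/-. Each of the 4 groups (aorta and macrophages of either strain) held 10 arrays, and each array carried its own mouse number. No paired analysis was possible because the groups share no mouse numbers. The series record speaks of 10 congenic mice, which leaves open whether a mouse gave both tissues, and the fit of all 40 arrays took them as independent. The labels do not give the ends of the donor segment, the source of the macrophages or the sex of the mice. Median array intensity ran from 68.8 to 74.7 in aorta and from 42.5 to 46.8 in macrophages. The mean correlation of an array with the others of its group, across probe sets, ran from 0.983 to 0.994. The number of arrays is among the limits of the precision. The arrays also parted into a set with high Xist and a set with high Eif2s3y, transcripts of the X and the Y chromosome. Both aorta groups and the control macrophages held 5 arrays of each set, and the congenic macrophages held 6 with high Xist and 4 with high Eif2s3y.

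Control macrophages were compared with control aorta to check that the arrays carried the markers of their tissue. Smooth muscle, endothelial and fibroblast markers were far lower in macrophages, and most macrophage markers were higher. Acta2, the actin of smooth muscle, Mylk, the myosin light chain kinase, and Dpt, a matrix protein of fibroblasts, lay in macrophages below the lower quartile of the probe sets (3.85 on the log2 scale). Counted from that quartile, they were lower by a log2 difference of at least -9.17, -9.52 and -9.47. Tek, a receptor of endothelial cells, differed by -7.80, to a macrophage level of 3.90. Fcer1g and Aif1, both expressed by macrophages, were higher by 2.29 and 2.28. All 12 measured smooth muscle markers were lower over all genes and when adjusted over the list alone (12), with a camera adjusted p of 1.36e-08 and adjusted p = 0.00244 with an estimated correlation. All 14 endothelial markers were lower (14 adjusted over the list alone), with a camera adjusted p of 1.37e-07 and adjusted p = 0.00325 with an estimated correlation. The 9 fibroblast markers were lower as well (9 adjusted over the list alone), with a camera adjusted p of 3.65e-06 and adjusted p = 0.0082 with an estimated correlation. Of 12 macrophage markers, 11 were higher and 1 lower over all genes (Lyz2, a lysozyme, with -1.19, near the lowest values of the arrays in both tissues and named after its value was seen), and 11 and 1 when adjusted over the list alone. The camera adjusted p of that list was 1.21e-08, and it was lost with adjusted p = 0.0612 with an estimated correlation. Markers of other cell types were present as well. Of 9 B and plasma cell markers 6 were higher and 2 lower in macrophages over all genes and when adjusted over the list alone (6 and 2), with a camera adjusted p of 0.000308 and adjusted p = 0.16 with an estimated correlation. Among them, Ms4a1 lay at 9.60 in macrophages and 5.38 in aorta, and Cd79b at 10.03 and 7.06. In control aorta, adipocyte markers were high (Adipoq 12.75 and, of brown fat, Cidea 12.08), as were Cytl1 of cartilage (12.74) and Myh6 of heart muscle (13.11). In limma, 15523 of 19147 genes differed, 4040 higher and 11483 lower in macrophages. The columns of the tissues appear to have been normalised separately: with each array centred on its median, 11220 genes were higher and 5382 lower, and the median difference over all genes moved from -0.33 to 0.34.

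The series title links a locus to Cdkn2a, the gene of a cyclin-dependent kinase inhibitor and of the ARF protein, so Cdkn2a and its neighbour Cdkn2b were compared in both tissues. Both lie on chromosome 4 in the GRCm38.p6 assembly. Cdkn2a fell 5.73-fold in congenic macrophages (95% interval 4.34 to 7.57), from a log2 intensity of 6.78 ± 0.56 to 4.26 ± 0.34 (SD, n = 10 in each group). All 10 congenic arrays lay below every control array, and the geometric mean intensity was 19.2 against 110. The log2 fold change was -2.52 (SE 0.19), with a limma adjusted p of 1.71e-08. A two-sided permutation test gave p = 2e-05, the smallest that 100000 resamples can give. In aorta, Cdkn2a was 5.54 ± 0.27 in control and 5.09 ± 0.36 in congenic mice (SD, n = 10 in each group), and 4 of 10 congenic arrays lay below every control array. That log2 fold change of -0.45 (SE 0.13) did not pass the test over all genes (limma adjusted p = 0.0703), while the permutation test of this gene alone gave p = 0.00472. With array weights in the limma fit, the aortic difference passed (adjusted p = 0.0449). The macrophage effect exceeded the aortic effect by a log2 difference of -2.07 (95% interval -2.56 to -1.58), with a limma adjusted p of 2.67e-07 for the difference, while control aorta lay only 1.16 above the lower quartile of its probe sets, which left less room to fall.

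Cdkn2b, a cyclin-dependent kinase inhibitor next to Cdkn2a, did not pass the test in either tissue. Its log2 intensity in macrophages was 8.30 ± 0.96 in control and 8.79 ± 0.74 in congenic mice (SD, n = 10 each), with a limma adjusted p of 0.52 and a permutation p of 0.208. In aorta its log2 fold change was 0.17, with a limma adjusted p of 0.662 and a permutation p of 0.345. Among 11 measured genes around Cdkn2a, 1 rose and 4 fell in macrophages, and 2 rose and 5 fell when adjusted over the list alone. This list went down with a camera adjusted p of 0.0198, and adjusted p = 0.188 with an estimated correlation. With fry it went down as well (adjusted p = 2.0e-07). Mllt3, a subunit of transcription elongation complexes, fell with a log2 fold change of -0.92 (limma adjusted p = 2.98e-06) and Tusc1 fell with -0.90 (3.83e-06). Klhl9, an adaptor of a ubiquitin ligase named after its value was seen, rose with 0.38 (0.0155). Mtap, the methylthioadenosine phosphorylase of the methionine salvage pathway, had -0.33 (0.00753). In aorta, 1 gene of the list rose and 2 fell (1 and 3 adjusted over the list alone). The camera adjusted p was 0.094, with adjusted p = 0.14 with an estimated correlation and 0.0156 with fry. There Mllt3 had a log2 fold change of -0.45 (limma adjusted p = 0.00766), Mtap -0.28 (0.00995) and Dmrta1 0.67 (0.00949), the last from 3.11 ± 0.19 in control mice, and below the lower quartile of the probe sets in both strains, so that the size of its rise is uncertain.

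**Figure D1:**
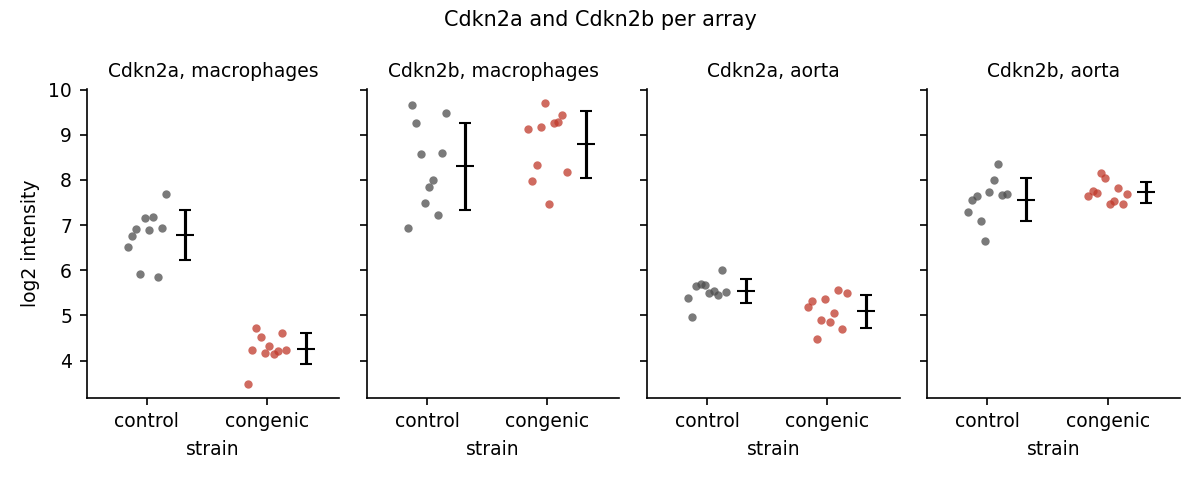
Log2 intensity of Cdkn2a and Cdkn2b on each array of control (grey) and congenic (red) mice, with the mean and SD of the 10 arrays of a group as bars. The congenic macrophages lie between 3.48 and 4.71 for Cdkn2a and the control macrophages between 5.86 and 7.69.

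The share of called genes on chromosome 4 was compared with the rest of the genome, because the congenic segment lies there. In macrophages 116 of 1116 measured genes on chromosome 4 passed the test (10.4%), against 203 of 17795 elsewhere (1.14%). The odds ratio was 10.05 (95% interval 7.86 to 12.8), with a two-sided Fisher exact p of 3.7e-61. The chromosome with the next highest share was chromosome 12, with 1.97%. In aorta, 133 of 1116 genes on chromosome 4 passed (11.9%) against 443 of 17795 elsewhere, with an odds ratio of 5.30 (4.29 to 6.52) and a Fisher exact p of 3.69e-44. Gene order was taken from the GRCm38.p6 assembly. In macrophages, 113 of the 116 calls lay in a continuous span of 494 measured genes from Cntln to Zfp46. This span was drawn after the calls were seen, from the first to the last gene called in both tissues with the same sign. Within it 22.9% of genes were called, 36 up and 77 down, against 3 of 622 genes on the rest of the chromosome. In aorta, whose calls also set the ends of the span, 119 calls lay in it and 14 outside it. In that span, the share called in macrophages was 3.64% in the dimmest of 3 equal groups of genes, 27.4% in the middle group and 37.6% in the brightest.

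Single genes on chromosome 4 differed by far more than the spread between mice in both tissues. Cap1, an actin-regulating protein, fell 7.35-fold in congenic macrophages (95% interval 6.77 to 7.99; limma adjusted p = 3.83e-19), from 11.69 ± 0.12 to 8.81 ± 0.13 on the log2 scale (SD, n = 10 each). It fell 6.89-fold in congenic aorta (6.07 to 7.82; adjusted p = 1.85e-15), and all 10 congenic arrays lay below every control array in both tissues. Tceanc2 fell in macrophages with a log2 fold change of -1.66 and in aorta with -1.62, and Ccdc163 with -1.67 and -1.40. In macrophages, Lepr, the leptin receptor, rose 58.4-fold (30.04 to 114; adjusted p = 2.48e-08), from 6.01 ± 1.53 to 11.88 ± 0.38. Control mice varied widely for Lepr, and a dimmer probe set of the gene, close to the lowest values of the arrays, had a log2 fold change of 0.29. In aorta, Lepr rose 1.88-fold (adjusted p = 8.44e-07), with a log2 fold change of -0.15 for its other probe set.

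Further falls in macrophages included Tcea3, a transcription elongation factor, with a log2 fold change of -2.86 (limma adjusted p = 6.89e-09) and Skint3 (9.6e-08), which reached 2.54 ± 0.14 in congenic mice, below the lower quartile of the probe sets, and fell by at least -1.40 counted from that quartile. Rims3, a synaptic protein, had -1.91 and Itgb3bp, a centromere protein, -1.86, while other probe sets of these genes gave -0.19 and -0.37. Itgb3bp reached 3.88 in congenic mice, close to the lower quartile of 3.85, so the size of its fall is uncertain. Oscp1 had -1.57, with -1.75 for its other probe set. Among the rises were Acer2, a ceramidase of the Golgi, with 2.46 (limma adjusted p = 1.4e-08), Ubxn11 with 1.59, Hyi with 1.48, Wdr78 with 1.45 and Ccdc17 with 1.32. For each of these 5 rises, all 10 congenic arrays lay above every control array.

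In congenic aorta, Echdc2, a mitochondrial protein of the enoyl-CoA hydratase family, fell with a limma adjusted p of 2.4e-18. Its log2 intensity was 10.14 ± 0.15 in control and 3.78 ± 0.45 in congenic mice (SD, n = 10 each), the latter below the lower quartile of the aortic probe sets (4.38), so that the size of the fall is given against that quartile only, as at least 54.1-fold. In macrophages it lay near the lowest values in both strains, with a log2 fold change of -0.18 (adjusted p = 0.283). Efcab7 fell with a log2 fold change of -1.96 (5.29e-08) and Ago4, an argonaute protein, with -1.14 (0.00493). Ccdc17 rose 4.90-fold (1.01e-13), Wdr78 rose 3.05-fold (8.81e-08), and Fgr, a Src family kinase of myeloid cells, rose 4.81-fold (6.05e-12). In macrophages the log2 fold change of Fgr was 0.96 (1.84e-11). Csf3r, the receptor of granulocyte colony-stimulating factor, rose in both tissues, 1.45-fold in macrophages (0.000194) and 2.33-fold in aorta (3.99e-06).

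**Figure D2:**
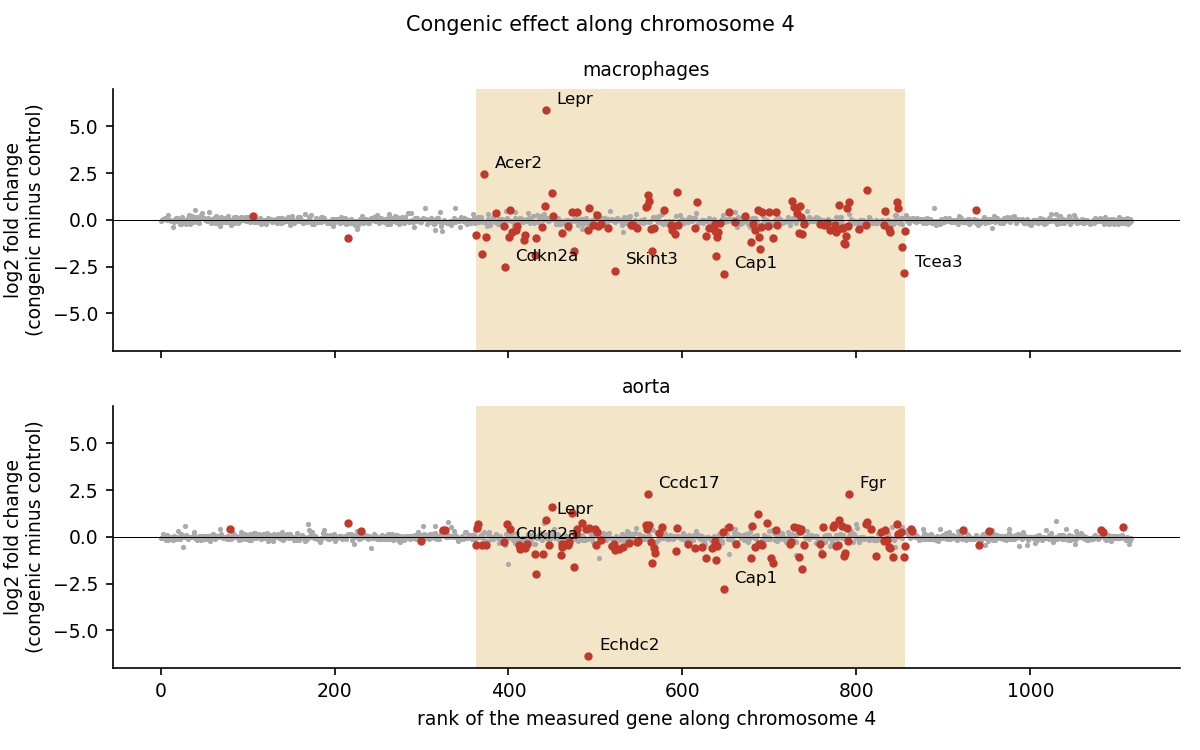
Log2 fold change (congenic minus control) of each measured gene on chromosome 4, in its order along the chromosome, in macrophages and in aorta, with genes past an adjusted p of 0.05 in red and the span from Cntln to Zfp46 shaded. The shaded span holds 113 of the 116 calls in macrophages and 119 of the 133 calls in aorta.

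Congenic and control macrophages were then compared across all genes, to find changes beyond the donor segment. Outside chromosome 4, Calml4, a calmodulin-like protein, rose 2.36-fold (95% interval 1.89 to 2.95), with all 10 congenic arrays above every control array. Cp, the copper-binding ferroxidase ceruloplasmin, rose 1.98-fold (1.55 to 2.53), and Prok2, a secreted prokineticin, rose 3.01-fold (1.94 to 4.68). Anpep, an aminopeptidase of the cell surface, fell with a log2 fold change of -0.74, and Lgals3, a galactoside-binding lectin, with -0.43. In limma, 319 of 19147 genes passed the test, 124 up and 195 down, of which 86 rose and 117 fell off chromosome 4. The limma adjusted p was 3.37e-05 for Calml4, 0.002 for Cp, 0.0072 for Prok2, 0.00131 for Anpep and 0.0203 for Lgals3. Sfrp1, a secreted Wnt antagonist, rose with a log2 fold change of 1.26 (adjusted p = 0.0235) and Tmem117 with 1.22 (0.021). Tns1, a protein of focal adhesions, fell with -0.79 (0.0283), Galnt6, an enzyme of O-glycosylation, with -0.62 (0.0353) and Ttyh2 with -0.60 (0.00379). With the genes of chromosome 4 left out of the adjustment, 69 of the 203 calls elsewhere remained, 32 up and 37 down, and Sfrp1 (adjusted p = 0.0517), Tns1 (0.0545) and Galnt6 (0.0585) no longer passed. Within the arrays of high Xist 50 genes passed, 1 of them off chromosome 4, within those of high Eif2s3y 85 passed, 26 of them off chromosome 4, and with the set as a covariate 281 passed.

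In congenic macrophages few members of the gene lists passed the test singly, and no list passed with an estimated correlation. With fry 3 lists passed, namely the genes around Cdkn2a, transforming growth factor beta response genes and ribosomal protein genes. Transforming growth factor beta response genes had a median log2 fold change of 0.16, with 13 of 15 members positive, and cholesterol synthesis genes had 0.16, with 16 of 18 positive. Interferon response genes had -0.21, with 22 of 25 negative. No member of the growth factor list passed limma over all genes, and 3 rose when adjusted over the list alone. Its camera adjusted p was 0.00211, with adjusted p = 0.188 with an estimated correlation. Tgfbr2, a receptor of that pathway, had a log2 fold change of 0.16 (limma adjusted p = 0.0877) and Smad7, its inhibitor, 0.34 (0.112). For cholesterol synthesis, no member passed over all genes or when adjusted over the list alone, with a camera adjusted p of 0.00346 and adjusted p = 0.754 with an estimated correlation. Hsd17b7 had a log2 fold change of 0.55 (limma adjusted p = 0.171) and Insig1 0.14 (0.258). The interferon list went down with a camera adjusted p of 0.0264 and adjusted p = 0.85 with an estimated correlation, and no member passed over all genes or when adjusted over the list alone. Rsad2, an antiviral protein, had -0.69 (limma adjusted p = 0.208) and Oasl1 -0.61 (0.179).

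Targets of p53, ribosomal protein genes and macrophage markers had small positive medians in congenic macrophages, and none of these lists passed with an estimated correlation. For the 24 p53 targets the median was 0.10, no member passed over all genes or adjusted over the list alone, and the camera adjusted p was 0.00346, with adjusted p = 0.397 with an estimated correlation. Cdkn1a, a cyclin-dependent kinase inhibitor induced by p53, had a log2 fold change of 0.24 (limma adjusted p = 0.118). Of 16 ribosomal protein genes 1 rose, Rpl23 with 0.24 (0.00905), and 3 rose when adjusted over the list alone, with a camera adjusted p of 0.00384 and adjusted p = 0.392 with an estimated correlation. For 12 macrophage markers, none passed over all genes or adjusted over the list alone, the median was 0.078 and the camera adjusted p was 0.0185, with adjusted p = 0.439 with an estimated correlation. Adgre1, a surface receptor of macrophages, had 0.22 (limma adjusted p = 0.126). Inflammatory and cytokine genes had a median of 0.074 and a camera adjusted p of 0.0198, with adjusted p = 0.559 with an estimated correlation, and none of 24 passed over all genes or adjusted over the list alone. Il6 had 0.96 (limma adjusted p = 0.153) and Tnf -0.30 (0.242). Of 21 immediate early genes 1 fell over all genes, the transcription factor Jun on chromosome 4 with -0.51 (0.048), and 1 rose and 1 fell adjusted over the list alone. The camera adjusted p of that list was 0.687, with adjusted p = 0.889 with an estimated correlation.

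Congenic and control aorta were compared across all genes in the same way. Lists of inflammation, macrophages, matrix proteases and the cell cycle had positive medians in congenic aorta and passed camera at the preset correlation. Of their genes, 7 of 24, 6 of 12, 8 of 21 and 6 of 34 passed singly. No list passed with an estimated correlation, while 12 passed with fry, these among them. Striated muscle markers had a median of -0.58, and smooth muscle, endothelial and fibroblast markers had medians between -0.0066 and 0.013. Chil3, a chitinase-like protein secreted by macrophages, rose 4.18-fold (95% interval 2.40 to 7.27), and Saa3, a serum amyloid protein, rose 4.86-fold (2.51 to 9.40). Mmp12, the macrophage elastase, rose 1.77-fold (1.51 to 2.08), from 11.44 ± 0.34 to 12.27 ± 0.15 on the log2 scale (SD, n = 10 each), with all 10 congenic arrays above every control array. In limma 577 of 19147 genes passed, 436 up and 141 down, and off chromosome 4 378 rose and 66 fell, 1 of these 444 being a gene without a known chromosome. The limma adjusted p was 0.0038 for Chil3, 0.00688 for Saa3 and 0.000128 for Mmp12. Srrm4, a splicing regulator, fell with -0.72 (0.025), while its other probe sets gave 0.02 and 0.07. Within the arrays of high Xist 86 genes passed (68 of the 577), within those of high Eif2s3y 183 passed (139 of the 577), and with the set as a covariate 686 passed (576 of the 577). With the mean of the macrophage markers as a covariate, 68 genes passed, 15 of them off chromosome 4. That mean was itself higher in congenic aorta, by 0.33 on the log2 scale. The fit therefore cannot tell whether macrophage content accounts for the calls it removes.

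Inflammatory and cytokine genes had a median log2 fold change of 0.48 in aorta, with 23 of 24 members positive. Over all genes 7 rose and none fell, and 16 rose when adjusted over the list alone, with a camera adjusted p of 1.06e-12 and adjusted p = 0.123 with an estimated correlation. Il1rn, the antagonist of the interleukin-1 receptor, rose 2.37-fold (limma adjusted p = 0.000779), Sele, an endothelial adhesion molecule, had a log2 fold change of 0.67 (0.00203) and Il1a 0.58 (0.00819). Il6 rose 4.23-fold with a wide interval (1.86 to 9.59; 0.0483), and 2 of 10 congenic arrays lay above every control array. Without the genes of chromosome 4 in the adjustment, Il6 no longer passed (adjusted p = 0.0594), nor did Retnlg (0.0518). Of 10 neutrophil markers 4 rose over all genes and 4 adjusted over the list alone, with a median of 0.43, a camera adjusted p of 0.00017 and adjusted p = 0.137 with an estimated correlation. Without mouse 19, an array left out after its values were seen, 2 of the 4 remained, and S100a9 (adjusted p = 0.0602) and Retnlg (0.0676) no longer passed. Among them, S100a8 rose 3.31-fold (0.0261) and S100a9, its partner in calprotectin, 3.86-fold (0.0373). Lcn2, an iron-siderophore binding protein, rose 2.52-fold (0.0209), and Retnlg, a resistin-like protein, had a log2 fold change of 1.44 (0.0416). Outside the lists, Clec4d, a C-type lectin receptor of myeloid cells, rose (0.00647), and Tnfsf11, the ligand of RANK, rose (0.0261). Both lay below the lower quartile of the probe sets in control aorta, and counted from it the rises were at least 2.62-fold and 2.79-fold. Tnfsf11 had a log2 fold change of 0.14 for its dimmer probe set.

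Macrophage markers had a median of 0.37 in aorta, and 6 of 12 rose over all genes. Adjusted over the list alone, 11 rose and 1 fell (Lyz2, with a log2 fold change of -0.13), with a camera adjusted p of 2.35e-09 and adjusted p = 0.123 with an estimated correlation. Of the 12 markers 3 lie on chromosome 4. Tyrobp, a signalling adaptor of myeloid receptors, rose 1.31-fold (limma adjusted p = 0.00573), and Mpeg1, a pore-forming protein, 1.34-fold (0.00636). Of 18 inflammatory monocyte genes 10 rose over all genes and 13 adjusted over the list alone, with a median of 0.39, a camera adjusted p of 2.35e-09 and adjusted p = 0.0885 with an estimated correlation. In that list, which holds Chil3, S100a8 and S100a9 as well, Ccr2, a chemokine receptor of monocytes, rose 1.87-fold (0.00618). Of 8 dendritic cell markers 1 rose over all genes, Itgax with 1.67-fold (0.00158), and 4 adjusted over the list alone, with a camera adjusted p of 0.00017 and adjusted p = 0.123 with an estimated correlation. Genes of MHC class II had a median of 0.36 and all 9 were positive, with none passing over all genes and 4 rising adjusted over the list alone. Their camera adjusted p was 0.000121, with adjusted p = 0.348 with an estimated correlation, and Cd74, the invariant chain, had a log2 fold change of 0.19 (limma adjusted p = 0.176).

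Of 21 matrix protease genes 8 rose over all genes and 13 adjusted over the list alone, with a median of 0.34, a camera adjusted p of 2.35e-09 and adjusted p = 0.0885 with an estimated correlation. Ctsl, the lysosomal cathepsin L, rose 1.27-fold (limma adjusted p = 0.00461) and Mmp8, a collagenase of neutrophils, 2.49-fold (0.00618). Of 18 lipid uptake and foam cell genes 6 rose over all genes and 9 adjusted over the list alone, with a median of 0.17. The camera adjusted p of that list was 8.28e-06, with adjusted p = 0.0885 with an estimated correlation. Msr1, a scavenger receptor, rose 1.69-fold (limma adjusted p = 0.00125), Fabp5, a fatty acid binding protein, 1.65-fold (0.00219), Trem2, a lipid-sensing receptor, 1.57-fold (0.00404) and Lgals3 1.47-fold (0.0122). Of 15 targets of LXR and genes of cholesterol efflux 3 rose over all genes and 4 adjusted over the list alone, with a camera adjusted p of 0.00407 and adjusted p = 0.137 with an estimated correlation. Apoc2, the cofactor of lipoprotein lipase, rose 1.78-fold (0.0106), Abcg1, a cholesterol exporter, 1.29-fold (0.0119) and Npc2, a cholesterol carrier of lysosomes, 1.14-fold (0.0286). Of 34 cell cycle genes 6 rose over all genes and 18 adjusted over the list alone, with a median of 0.31, a camera adjusted p of 1.59e-12 and adjusted p = 0.123 with an estimated correlation. Without mouse 19, 2 of the 6 passed, with Nusap1 (adjusted p = 0.0522) and Bub1b (0.0631) among those lost, and 3 passed without the genes of chromosome 4 in the adjustment (Bub1b 0.0505). Plk1, a mitotic kinase, rose 1.28-fold (0.0046), and Nusap1, a spindle protein (0.0309), and Ccnb2, a mitotic cyclin (0.0332), rose 1.37-fold each.

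Lymphocyte markers had medians of 0.18 for B and plasma cells and 0.17 for T and NK cells in aorta. Of 9 B and plasma cell markers 2 rose over all genes, Fcrla with 1.92-fold (limma adjusted p = 0.00165) and Mzb1 with 1.73-fold (0.00753), and 3 adjusted over the list alone. The camera adjusted p was 0.0103, with adjusted p = 0.137 with an estimated correlation, and Jchain had a log2 fold change of 2.40 (limma adjusted p = 0.0615). No T and NK cell marker passed over all genes or adjusted over the list alone (11 measured), with a camera adjusted p of 0.0103, adjusted p = 0.537 with an estimated correlation, and Cd3d at 0.52 (limma adjusted p = 0.124). The markers of vessel wall cells had medians of -0.0066 for smooth muscle (12 genes; camera adjusted p = 0.634), -0.0055 for endothelium (14 genes; 0.665) and 0.013 for fibroblasts (9 genes; 0.785), and no member passed over all genes or adjusted over the list alone. With an estimated correlation each of these 3 lists had adjusted p = 0.925. Markers of striated muscle, a tissue outside the vessel wall, had a median of -0.58, with 15 of 16 negative. No striated muscle marker passed over all genes or adjusted over the list alone, the camera adjusted p was 0.000863, with adjusted p = 0.501 with an estimated correlation, and Ckm, the creatine kinase of muscle, had -1.13 (limma adjusted p = 0.268). The mean over the inflammatory, macrophage and cell cycle lists (70 genes) was 7.97 ± 0.13 in control and 8.36 ± 0.30 in congenic aorta (SD, n = 10 each), and mouse 19 had the highest value, 9.15. Without mouse 19, chosen after the values were seen, 519 genes passed, 468 of the 577 remained, and the T and NK cell list no longer passed (camera adjusted p = 0.0681).

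**Figure D3:**
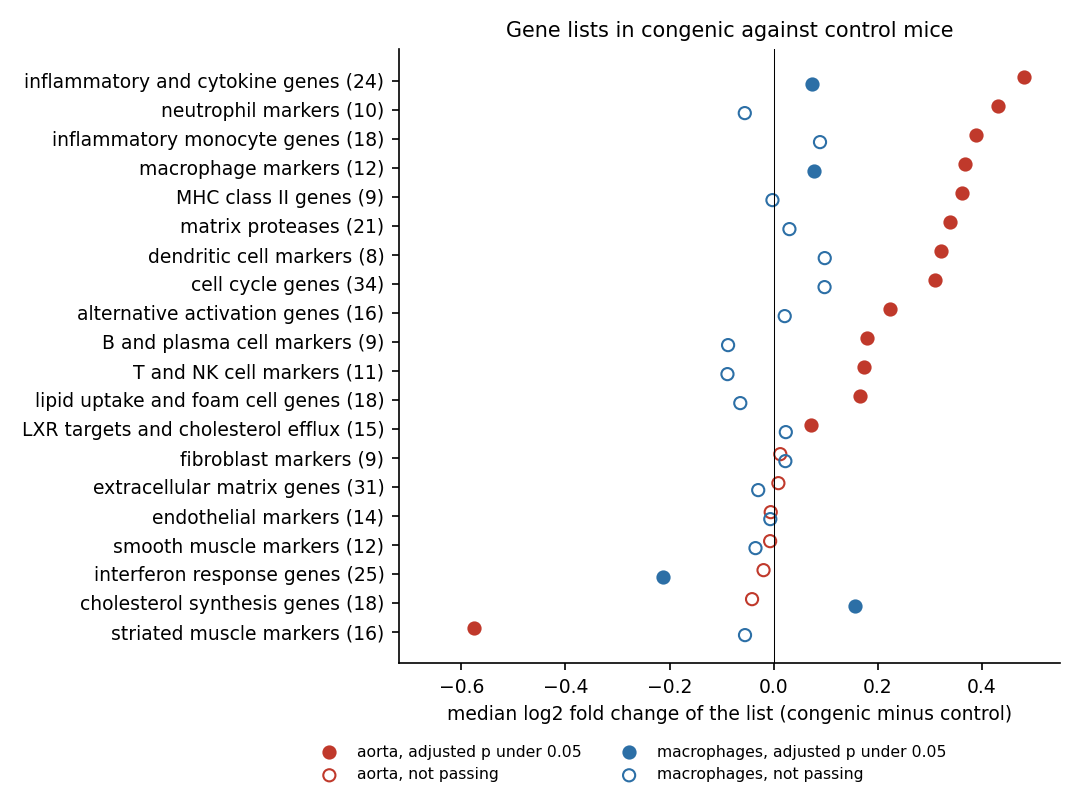
Median log2 fold change (congenic minus control) of 20 gene lists in aorta (red) and in macrophages (blue), with the number of measured genes in brackets and filled points for lists with a camera adjusted p under 0.05 at the preset correlation. Inflammatory and cytokine genes lie at 0.48 in aorta and 0.074 in macrophages, and striated muscle markers at -0.58 in aorta.

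**Figure D4:**
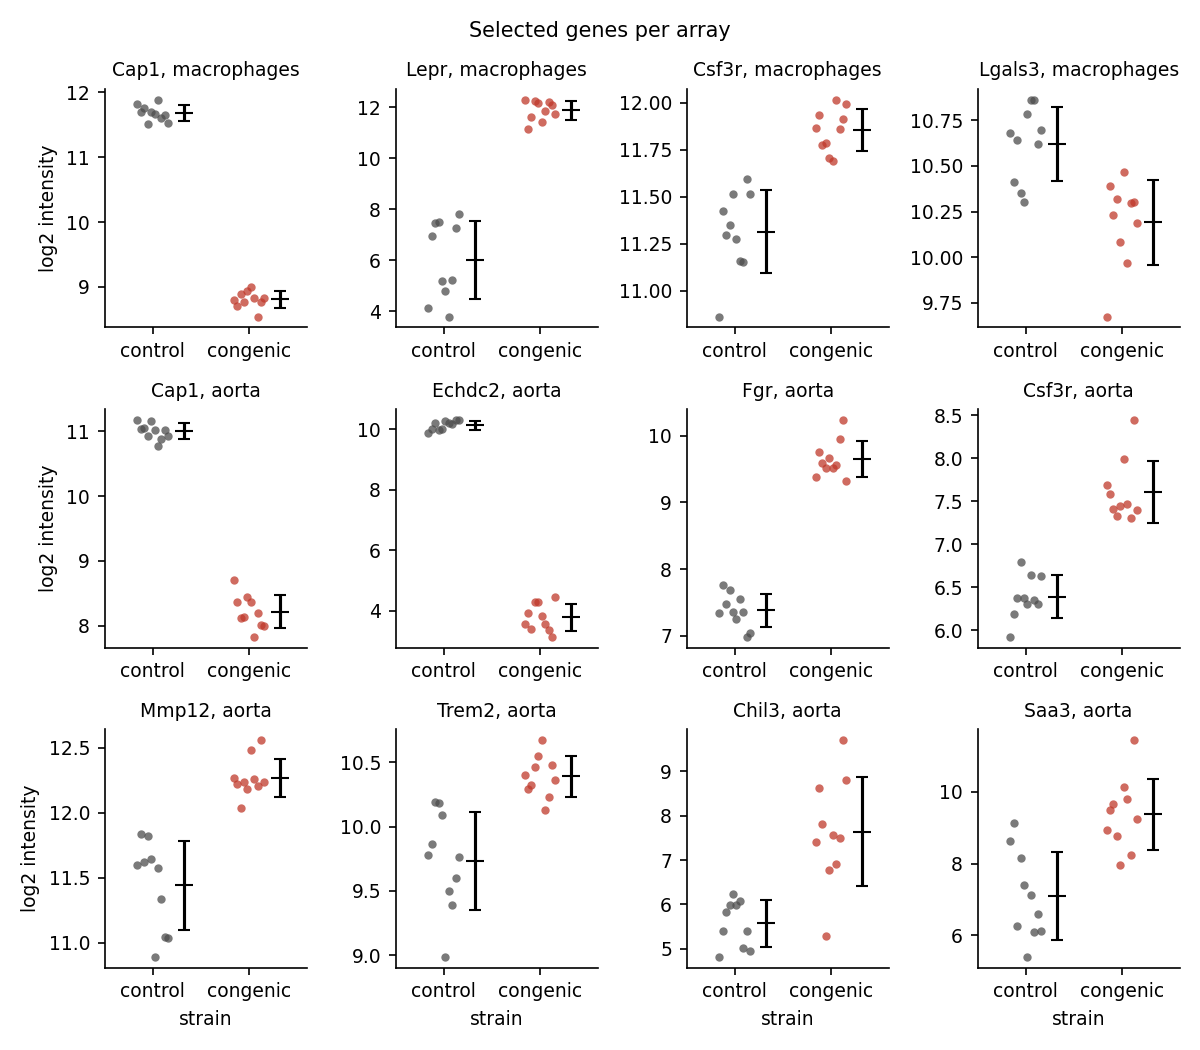
Log2 intensity of selected genes on each array of control (grey) and congenic (red) mice, with the mean and SD of 10 arrays as bars and an axis of its own, not starting at 0, for each gene. Echdc2 lies at 10.14 in control and 3.78 in congenic aorta, and Mmp12 at 11.44 and 12.27.

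The congenic effects of the tissues were compared by the interaction of strain and tissue. On chromosome 4, the effects on Echdc2 differed by 6.18, but in macrophages it lay near the lowest values in both strains, where no fall could be read. Svbp, which binds vasohibin, rose in macrophages with a log2 fold change of 0.94 and had 0.03 in aorta. Acer2 rose with 2.46 in macrophages and had 0.27 in aorta, and the rise of Lepr was larger in macrophages by 4.96. The rise of Fgr was larger in aorta, by a difference of -1.31 (macrophages minus aorta). In limma 435 genes differed in their congenic effect, 97 with a higher and 338 with a lower value in macrophages, and 82 of them lay on chromosome 4. The limma adjusted p of the difference was 1.34e-27 for Echdc2, 3.28e-11 for Svbp, 1.52e-09 for Acer2 and for Fgr, and 3.2e-09 for Lepr. Hyi had a difference of 0.98, Trim62, a ubiquitin ligase, 0.88 and Fuca1, the lysosomal fucosidase, 0.46. Cyp2j6, a cytochrome of the P450 family, differed (3.28e-11), with congenic macrophages below the lower quartile of the probe sets and a difference of -1.50 counted from that quartile. This was on another probe set than the one used for macrophages alone, where it fell with -1.09. Cd52, a surface protein of lymphocytes and macrophages, had -0.93 (8.73e-08), with a fall of -0.26 in macrophages and a rise of 0.67 in aorta.

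Lipid uptake and foam cell genes differed between the tissues, with a median difference of -0.30 (macrophages minus aorta). Over all genes 1 member was higher and 6 lower, and 1 and 12 adjusted over the list alone, with a camera adjusted p of 5.8e-07 and adjusted p = 0.0438 with an estimated correlation. Macrophage markers had a median difference of -0.28, with 1 higher and 3 lower over all genes and 1 and 7 adjusted over the list alone. The camera adjusted p was 0.000197, with adjusted p = 0.29 with an estimated correlation. Neutrophil markers had -0.54, with 3 lower over all genes and 4 adjusted over the list alone, a camera adjusted p of 0.000284 and adjusted p = 0.177 with an estimated correlation. Inflammatory and cytokine genes had -0.39, with 2 lower over all genes and 3 adjusted over the list alone, a camera adjusted p of 0.000426 and adjusted p = 0.427 with an estimated correlation. In all, 13 lists passed with the preset correlation and 9 with fry.

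The congenic calls of the tissues were compared to find genes called in both. Of the genes called in both tissues, 26 rose in both and 40 fell in both. On chromosome 4 there were 25 rises and 40 falls, against 1.97 and 5.24 expected from the product of the counts there. That expectation, like the one for opposite directions, spreads the calls over all 1116 genes of the chromosome. Most calls lay in the span from Cntln to Zfp46, so it is too low. A probe mismatch with a donor allele would give shared falls as well. Off chromosome 4, Mctp2, a membrane protein with C2 domains, rose in both tissues, with 0.88 in macrophages and 0.78 in aorta. This 1 shared rise stood against 1.80 expected there, and no fall was shared, against 0.43 expected. Shared calls off chromosome 4 were thus no more frequent than the product of the counts gives. A further 5 genes off chromosome 4 fell in macrophages and rose in aorta. Lgals3 had -0.43 and 0.55, Galnt6 -0.62 and 0.66, Arhgap9 -0.21 and 0.43, Atp6v1c1 -0.33 and 0.24, and Rnh1 -0.30 and 0.20. With the genes of chromosome 4 left out of the adjustment, Lgals3 still passed in macrophages (adjusted p = 0.0479), as did Mctp2 (0.0147), while Atp6v1c1 (0.0545) and Galnt6, Arhgap9 and Rnh1 (0.0585 each) did not. On chromosome 4, 3 genes were called in opposite directions. Cd52 had -0.26 and 0.67, Stra6l -0.96 and 0.75, and Eva1b 0.40 and -0.41. Genes called in opposite directions numbered 3 against 6.61 expected on chromosome 4 and 5 against 2.77 elsewhere. Mctp2, Arhgap9, Atp6v1c1, Rnh1, Stra6l and Eva1b were named after their values were seen. Across genes, which are not independent replicates, the log2 fold changes of the tissues had a Pearson correlation of 0.42 on chromosome 4 and 0.099 elsewhere. The Spearman correlation was lower on chromosome 4, with 0.26, and was 0.092 elsewhere.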

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

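The striated muscle test, the Cdkn2a probe test and the repeats of the macrophage gene test were chosen after the results were seen. In 234 tests of a single array standing far from the others of its group, 20 gave such an array, where chance flags about 1 in 20 groups. In aorta of congenic mice, mouse 19 stood highest for Apoc2 (10.12, next 9.163), Cd3d (9.578, next 8.573), Cd52 (12.11, next 11.75), Cd74 (13.49, next 13.17) and Clec4d (7.914, next 6.506), all on the log2 scale. Mouse 18 stood lowest for Ago4 (4.824, next 6.348) and Nusap1 (5.629, next 6.215) and highest for Atp6v1c1 (11.08, next 10.89). In aorta of control mice, mouse 2 stood highest for Il6 (8.016, next 5.78) and Sele (6.612, next 6.038), mouse 4 for Fcrla (5.515, next 4.82) and mouse 5 for Lyz2 (4.391, next 4.19), while mouse 9 stood lowest for Tceanc2 (9.245, next 9.585). The array of mouse 9 also had the lowest mean correlation with its group (0.9893, next 0.9917), as did that of mouse 21 in control macrophages (0.9855, next 0.9895). In control macrophages, mouse 25 stood highest for Prok2 (7.044, next 5.505) and Skint3 (7.23, next 6.00). In congenic macrophages, mouse 31 stood lowest for Cdkn2a (3.484, next 4.147), mouse 36 lowest for Svbp (9.538, next 9.839) and mouse 38 highest for Adgre1 (12.78, next 12.52).

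The congenic effect differed between the tissues, by the interaction test in limma, for 53 of 94 genes named in the text, which were in part chosen for large or opposite effects, and for 435 of 19147 genes in all. On chromosome 4 the differences (macrophages minus aorta, log2) were positive for Acer2 (2.19), Echdc2 (6.18, with macrophages at 3.06 and 2.88 and no room to fall), Eva1b (0.82), Fuca1 (0.46), Hyi (0.98), Lepr (4.96), Svbp (0.91), Trim62 (0.88) and Ubxn11 (0.81). They were negative for Ccdc17 (-0.97), Cd52 (-0.93), Cdkn2a (-2.07, with control aorta only 1.16 above the lower quartile and less room to fall), Csf3r (-0.68), Cyp2j6 (-2.00), Fgr (-1.31), Itgb3bp (-0.96), Oscp1 (-1.26), Skint3 (-1.99), Stra6l (-1.70), Tcea3 (-1.76) and Tusc1 (-0.89). Off chromosome 4, Calml4 (0.75), Lyz2 (0.32), Prok2 (1.599), Sfrp1 (1.16), Srrm4 (0.70) and Tmem117 (1.30) were positive. Negative differences off chromosome 4 included Chil3 at -2.49, Clec4d at -1.14, Fcrla at -1.03, Il1rn at -1.24, Mpeg1 at -0.46, Retnlg at -1.70, S100a8 at -1.70, S100a9 at -2.62, Saa3 at -2.21, Sele at -0.60 and Tyrobp at -0.34. Others were Abcg1 at -0.63, Apoc2 at -0.77, Fabp5 at -0.85, Lgals3 at -0.98, Mmp12 at -0.78, Msr1 at -0.68, Npc2 at -0.23 and Trem2 at -0.72. Further negative differences were those of Anpep (-1.003), Arhgap9 (-0.64), Atp6v1c1 (-0.57), Galnt6 (-1.28), Rnh1 (-0.50), Tns1 (-0.77) and Ttyh2 (-0.83). For Clec4d, Cyp2j6, Echdc2, Lyz2, Prok2, Sele and Skint3 at least 1 group lay below the lower quartile of the probe sets of its tissue. Itgb3bp lay close to it in congenic macrophages (3.88 against 3.85). The sizes of these differences are uncertain.

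Among gene lists, lipid uptake and foam cell genes had a median difference of -0.30 (camera adjusted p = 5.8e-07, and adjusted p = 0.0438 with an estimated correlation). The other 12 lists that passed with the preset correlation did not pass with an estimated correlation. Negative medians came from neutrophil markers (-0.54; adjusted p = 0.177 with an estimated correlation), inflammatory and cytokine genes (-0.39; 0.427), MHC class II genes (-0.37; 0.642), inflammatory monocyte genes (-0.33; 0.265), matrix proteases (-0.31; 0.177), macrophage markers (-0.28; 0.29) and cell cycle genes (-0.20; 0.827). Positive medians came from mast cell and basophil markers (0.57; 0.642), striated muscle markers (0.55; 0.642), cholesterol synthesis genes (0.22; 0.642), transforming growth factor beta response genes (0.17; 0.177) and ribosomal protein genes (0.068; 0.177). The median of striated muscle markers was -0.58 in aorta and -0.055 in macrophages. There the muscle genes Actc1 and Myh6 lay below the lower quartile of the probe sets in both strains, where no fall could be read. Of the 13842 probe sets that name no gene and stand outside the comparisons of genes, 54 passed limma in macrophages (22 up, 32 down) and 102 in aorta (59 up, 43 down). The 22 called in both tissues had the same sign in both.

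Each count of called genes was compared with 100 splits of the arrays into groups of the same sizes, the real split among them. The real split was the 1 that gave the highest count each time. It called 319 genes in macrophages against 13 in the highest other split, 577 in aorta against 2, and 435 for the difference between tissues against 4. This argues against chance for these totals. The totals hold 116 calls on chromosome 4 in macrophages and 133 in aorta, and the calls elsewhere were not tested on their own. Between control macrophages and control aorta the real split called 15523 against 12032. Random splits there still part the tissues unevenly, so their high counts point to a structure of the samples and do not show what chance would give.

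Calls lay on chromosome 4 far more often than elsewhere. Donor alleles that mismatch the probes could lower signals without a change in RNA. In macrophages, 67.2% of called chromosome 4 genes fell (95% interval 57.9 to 75.7), as mismatch would give. Other probe sets of called genes had the same sign in 81.6% of cases (65.7 to 92.3). Those of genes that fell were negative in 85.7% (63.7 to 97.0). Mismatch of single probe sets would not give this, but donor alleles that mismatch several probe sets of a gene would, so the test cannot decide. The intervals count probe sets as independent, though the 38 came from 30 genes. In aorta, 56.4% of called chromosome 4 genes fell (47.5 to 65.0). Within the span from Cntln to Zfp46, drawn after the calls were seen, 73 calls fell and 46 rose in aorta. In macrophages 77 fell and 36 rose there. Off chromosome 4, 66 aorta calls fell and 378 rose, while in macrophages 117 fell and 86 rose. The balance of falls and rises therefore does not set the tissues apart on mismatch. Other probe sets in aorta shared the sign in 57.5% (40.9 to 73.0). For genes that fell they were negative in 65.2% (42.7 to 83.6). Single mismatched probe sets would give both shares. Mismatch therefore stays open for called genes that fell, including those seen by a single probe set such as Cap1 and Echdc2. Donor alleles that change expression, the biological explanation the strain names give, stay open beside it.

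Leukocyte, inflammatory and cell cycle lists had positive medians in congenic aorta, with adjusted p = 0.123 with an estimated correlation for inflammatory, macrophage and cell cycle genes. A set of 155 genes outside the lists and off chromosome 4 was at least 8-fold higher in control macrophages than in control aorta. Its median log2 fold change in congenic aorta was 0.47 (95% interval 0.44 to 0.51). That interval came from resampling genes, so it does not measure the spread between mice. In 99 other splits of the aorta arrays the median ran from -0.32 to 0.34. The 106 genes picked on congenic arrays instead had 0.41. A larger share of macrophages or of other leukocytes would give this, as the macrophage samples also held the B cell marker Ms4a1 (9.60 against 5.38 in aorta). S100a9, which rose in aorta, was lower in control macrophages than in control aorta by -2.25. Of 10 neutrophil markers, 4 were higher and 5 lower in that contrast. The rise of the mean over the inflammatory, macrophage and cell cycle lists does not rest on a few arrays. On 10 of 10 congenic arrays this mean lay above the control median, though the highest control array (8.25) exceeded the lowest congenic array (8.18). Single lists were not tested in this way. Without mouse 19, 2 of 6 cell cycle calls and 2 of 4 neutrophil calls remained. The median over 35 smooth muscle, endothelial and fibroblast markers was 0.0053, against 0.37 for macrophage markers. Its interval (-0.034 to 0.011) came from resampling genes as well. These medians argue against less striated muscle raising every other cell type alike. A change of expression within cells of the congenic aorta stays open and was not tested, as does a difference between mice in dissection.

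Cdkn2a was lower in congenic macrophages and differed less in aorta. A probe mismatch with the donor allele would lower both tissues alike where there is room to fall. The effects differed by -2.07 (95% interval -2.56 to -1.58), but control aorta lay only 1.16 above the lower quartile of its probe sets on the log2 scale. The level of this probe set without Cdkn2a RNA is not known, so whether a fall as large as in macrophages could be seen there stays open. Mismatch and lower Cdkn2a expression therefore cannot be told apart, with a single probe set for the gene.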

How the results depend on the processing

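The tests within the Xist and Eif2s3y sets and with the macrophage marker covariate were chosen after the data were seen. Over all alternatives, a count of called genes or lists was taken as kept when within 1.5-fold of the main count, whatever the directions. Single values were kept when they held their sign and their side of the threshold. Among comparisons 78 were kept, 22 moved and 1 became stronger. Among genes or lists 2651 were kept, 244 weakened, 27 strengthened and 11 reversed. The contrast of control tissues with centred arrays was kept by its count, although 4040 higher and 11483 lower genes became 11220 and 5382. In macrophages the number of called genes went from 319 to 722 above the median signal, 508 with trend and robust variances, 757 with array weights and 541 with all 40 arrays in the fit, and to 69 without chromosome 4 genes, which drops 116 calls and, as their small p no longer enter the adjustment, 134 of the 203 elsewhere. It was 50 in the high-Xist arrays and 85 in the high-Eif2s3y arrays, where fewer arrays enter, 110 at an adjusted p of 0.01 and 74 with a fold change of at least 1.5. In aorta it went from 577 to 371 without chromosome 4 genes, and to 86 and 183 in the high-Xist and high-Eif2s3y arrays. It was 68 with the macrophage marker covariate, which itself differed between the strains, 217 at 0.01 and 174 at 1.5-fold. For the difference between tissues it went from 435 to 719 with array weights, 154 at 0.01 and 183 at 1.5-fold. Cdkn2a in aorta passed with array weights at -0.45 (adjusted p = 0.0449). With an estimated correlation 0 lists passed in macrophages, 0 in aorta and 1 for the difference, and with fry 3, 12 and 9 passed. On their dimmest probe sets, Ier3 (-0.22) and Tgfbr2 (-0.0053) turned negative in macrophages, and Rims3 (0.13), Srrm4 (0.021) and Ywhaz (0.17) turned positive in aorta. Ywhaz was 0.036 as the mean of its probe sets and 0.011 in the high-Eif2s3y arrays. In the high-Xist arrays of aorta, Cd5l (-0.015) and Tfrc (-0.0094) turned negative, and Myl2 (0.099) and Myl3 (0.051) positive. Where no cause is named, the cause was not tested. In the span of chromosome 4 around Cdkn2a, 10.9% of the dimmest genes were called in aorta and 32.1% of the brightest.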

Other observations

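The shared-gene test was chosen after the results were seen. Of 2 further lists that passed camera in congenic macrophages at the preset correlation, neither passed with an estimated correlation. All 10 mast cell and basophil markers were positive, with a median of 0.55, and none passed limma over all genes or adjusted over the list alone. Their camera adjusted p was 0.0386, with adjusted p = 0.754 with an estimated correlation. Mcpt4, a mast cell protease, had a log2 fold change of 0.97 (limma adjusted p = 0.432) and Fcer1a, a chain of the IgE receptor, 0.72 (0.577). Of 9 markers of resident peritoneal macrophages 8 were positive, with a median of 0.27, a camera adjusted p of 0.0402 and adjusted p = 0.559 with an estimated correlation, and none passed over all genes or adjusted over the list alone. Among them, Selp had 0.91 (limma adjusted p = 0.243) and Gata6, a transcription factor of these cells, 0.39 (0.366). Alox15 was higher in control macrophages than in control aorta by 6.47, and Lyve1 was lower by -5.24.

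In congenic aorta, 1 of 16 alternative activation genes rose over all genes, Chil3, and 5 rose adjusted over the list alone, with a median of 0.22. The camera adjusted p was 4.51e-05, with adjusted p = 0.135 with an estimated correlation. Ccl22, a chemokine, had a log2 fold change of 0.60 (limma adjusted p = 0.0705) and Ccl17 0.72 (0.0923). Mesothelial markers had a median of 0.23, and none of 8 passed over all genes or adjusted over the list alone, with a camera adjusted p of 0.0103 and adjusted p = 0.501 with an estimated correlation. Upk1b had 0.39 (limma adjusted p = 0.197) and Lrrn4 0.42 (0.219). Extracellular matrix genes (31) and interferon response genes (25) had medians of 0.0092 and -0.019, with camera adjusted p of 0.634 and 0.678, adjusted p = 0.925 with an estimated correlation for both, and no member past the threshold over all genes or adjusted over the list alone.

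The hypothesis that genes off chromosome 4 that rose in congenic aorta also rise in congenic macrophages was tested on all 378 of them. Their median log2 fold change in macrophages was 0.00064 (95% interval -0.016 to 0.016), and 190 were positive. The interval came from resampling genes, so it does not measure the spread between mice. The 378 genes were picked for their rise in aorta, so their shift there is no result of this test. No shift of these genes as a set was seen in macrophages.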
